A study of Mus musculus with 8 samples.

How the data were processed

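The series holds 8 samples of CD45+ immune cells sorted from brain tissue of C57BL/6 mice, from the 5xFAD line with and without intact Cxcr6. Per the labels' protocols, libraries were made with the 10x Chromium Single Cell Immune Profiling v2 kit. T cell receptor libraries were available for 4 samples, 2 per genotype, and the 4 gene expression samples were not analysed here. Cell Ranger 6.0 and the genome build mm10 are given per the submitters' processing notes, which do not state the command or the receptor reference. The deposited tables list assembled contigs with raw counts of reads and UMIs per contig, per the file headers, with no normalization. All 12792 deposited contigs were marked productive, high confidence and part of a cell, so cells that the submitters' pipeline did not call were not used here. All contigs were TRA or TRB chains.

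Group and replicate number were taken from the labels. The labels do not say whether replicate libraries are separate mice or pools. A usable cell had exactly 1 productive TRB chain and 1 or 2 productive TRA chains, which kept 5025 of 6686 barcodes (73.8% to 78.6% per library). Cells with 2 TRB chains were left out because they can be doublets. Cells of a library belonged to the same clone when the V segment, J segment and CDR3 nucleotides of the TRB were identical and at least 1 TRA chain, defined the same way, was shared. This gave 3384 clones, of which 446 were expanded (2 or more cells) and 2938 were single. Clone sizes depend on the number of cells sampled, so expanded shares, shares of the 10 largest clones and diversity indices were means of 1000 seeded draws of 567 cells, the number in the smallest library.

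Library values were compared between genotypes with exact two-sided permutation tests of the difference of means. Shares of single libraries carry 95% Clopper-Pearson intervals, and 0 counts carry the limit of 3 counts of the total. iNKT-like cells carried TRAV11 or TRAV11D joined to TRAJ18, and MAIT-like cells carried TRAV1 joined to TRAJ33. CD4 and CD8 lineages cannot be read from receptor chains and were not assigned. TRAJ segments were grouped as 58 to 40, 39 to 21 and 20 to 2. CDR3 hydrophobicity and charge left out the first and last 3 residues.

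Segment use was tested with edgeR's quasi-likelihood F test on the number of clones per V or J segment, with the log of the clone total as offset and no further scaling. The SE given with an edgeR fold change is its absolute value divided by the square root of the F statistic. For DESeq2 it is the SE of the Wald test. Of 164 segments seen, the 149 with at least 10 clones over the 4 libraries were tested, and p-values were adjusted by Benjamini-Hochberg over all of them with a threshold of 0.05. Expanded and single clones were compared in a model with the library as a block, and the interaction with genotype was tested in the same model. Shared sequences were compared with 10000 shuffles of library labels, with each sequence counted once per library before the shuffle. TRAV segments include near-identical copies whose assignment in the deposited tables is uncertain, and the label TRBV12-2+TRBV13-2 was kept as given. Coordinates are from GENCODE vM21 on GRCm38, the build that mm10 names.

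The named segments were chosen by a rule. It took every segment called in either edgeR test, the 5 TRAV, 5 TRBV, 3 TRAJ and 3 TRBJ segments with the highest mean share of clones, the 3 segments of each direction with the smallest p in the genotype test, and TRAV11, TRAJ18, TRAV1 and TRAJ33. Named clones were the 3 largest of each library and TRB amino-acid sequences found in 3 or more libraries. TRBV13-2 among iNKT-like cells, and the chains of cells with 2 TRB, fall outside this rule and were picked after their values were seen. The groups, tests, naming rule and first list of alternatives were fixed before the data were examined.

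The clone code was tested on simulated data with 411 clones of 531 cells, of which 0 were split and 0 merged, and the thinned share was off by 0.1 percentage points. The genotype test was tested on 20 simulated data sets with 20 of 149 segments changed, each with at least 40 clones and a dispersion of 0.01. It recovered 46.5% of 2-fold and 90.5% of 4-fold changes with a mean of 0.3 false calls. The same test of expanded against single clones recovered 29% of 2-fold and 73% of 4-fold changes with a mean of 0.35 false calls. The simulated dispersion was a setting and was not taken from the data. These rates therefore do not cover segments that vary more between libraries, such as TRAV11, with 20.3% and 12.9% of clones in the 5xFAD libraries.

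Alternatives covered the clone definition (TRB alone, the clonotypes of the deposited tables, amino-acid CDR3), the cells used (1 TRA only, at least 3 UMIs per chain, no iNKT-like or MAIT-like cells, no thinning), the diversity index (Shannon, Gini), the unit counted (cells, distinct chains, reads), the segment model (DESeq2, TMM scaling, no filter, joined TRAV copies, a replicate block, expansion at 3 or more cells), and leaving out each library in turn. Some alternatives were added after the data were seen: keeping cells with 2 TRB, dropping TRB chains with a short CDR3 first, clones by CDR3 nucleotides alone, leaving out the largest clones for the expanded share and the effective number, at least 3 UMIs per TRA for invariant cells, leaving out iNKT-like clones from the segment and J group results, crossed replicate numbers, and DESeq2 for the interaction. The work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.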

Results

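T cell receptor sequences were read from single CD45+ immune cells sorted from the brain parenchyma of 5xFAD mice and of 5xFAD;Cxcr6-/- mice. The 5xFAD line carries human amyloid precursor protein and presenilin transgenes with familial Alzheimer's disease mutations, and CXCR6 is a chemokine receptor found on tissue-resident T cells. The question, as the series title gives it, is how CXCR6 shapes the T cells that reside in the brain. Receptor libraries were available for 2 samples of each genotype. The 4 gene expression samples were not analysed here, so expression of Cxcr6 itself (GRCm38, chromosome 9, 123806475 to 123811760, protein_coding) could not be used to check the genotype labels. Every contig was a TRA or TRB chain, and 0 contigs came from other receptor chains, so gamma-delta T cells and B cells were outside the measurement.

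The 5xFAD libraries held 2069 and 2522 cell barcodes with a productive chain, and the 5xFAD;Cxcr6-/- libraries held 765 and 1330. Total UMIs were 32169 and 34772 in the 5xFAD libraries against 13460 and 22340 in the 5xFAD;Cxcr6-/- libraries. Reads per UMI ranged from 1069 to 2144. Cells with 1 TRB and 1 or 2 TRA chains, called usable cells, numbered 1527 and 1885 in the 5xFAD libraries and 567 and 1046 in the 5xFAD;Cxcr6-/- libraries. With 2 libraries against 2, the smallest p that an exact two-sided permutation test can give is 0.333, and 2 groups of 2 fail to overlap by chance in 33.3% of cases. The labels do not state whether the libraries of a genotype come from separate mice, so permutation p-values measure only the spread between these samples. The edgeR p-values rest on counts of clones, which are not replicates of a genotype, with a spread estimated jointly over segments. Intervals and limits of 0 counts cover counting error only.

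Fewer T cells with a paired receptor were recovered from the 5xFAD;Cxcr6-/- samples. The paired cells numbered 1609 and 1973 in the 5xFAD libraries and 628 and 1101 in the 5xFAD;Cxcr6-/- libraries. The mean was 1791 ± 257 (SD, n = 2) against 864.5 ± 334 (SD, n = 2), a difference of -926.5 cells (exact two-sided permutation p = 0.333). The number of sorted cells loaded per library was not given in the labels, so these counts describe depth and not T cell abundance in the brain.

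The brain T cells of both genotypes were clonally expanded, and less of the 5xFAD;Cxcr6-/- repertoire sat in expanded clones. A clone was a set of cells with the same TRB chain and at least 1 shared TRA chain, and a clone of 2 or more cells was called expanded. After every library was thinned to 567 cells, 37.4% and 36.7% of cells in the 5xFAD libraries were in expanded clones. In the 5xFAD;Cxcr6-/- libraries this share was 29.1% and 22.9%. Every 5xFAD value was above every 5xFAD;Cxcr6-/- value.

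The mean expanded share was 37.1% ± 0.530 (SD, n = 2) in 5xFAD and 26.02% ± 4.36 (SD, n = 2) in 5xFAD;Cxcr6-/-, a difference of -11.0 percentage points that exceeded the spread between replicates (exact two-sided permutation p = 0.333). Without thinning, the shares were 44.8% (95% Clopper-Pearson interval 42.3 to 47.3) and 49.9% (47.6 to 52.1) in 5xFAD. The unthinned shares were 29.1% (25.4 to 33.0) and 28.5% (25.8 to 31.3) in 5xFAD;Cxcr6-/-. Clones of 5 or more cells held 20.3% ± 4.06 of thinned cells in 5xFAD and 9.08% ± 1.37 in 5xFAD;Cxcr6-/- (SD, n = 2). The 10 largest clones held 23.7% and 16.6% of cells in 5xFAD, against 10.9% and 12.4% in 5xFAD;Cxcr6-/-, a mean difference of -8.49 percentage points (exact permutation p = 0.333). The effective number of clones, the inverse Simpson index, was 115 ± 86.2 in 5xFAD and 277 ± 13.8 in 5xFAD;Cxcr6-/- (SD, n = 2), a log2 difference of 1.51 (exact permutation p = 0.333).

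One library, through its largest clone, and 1 cell filter decided part of these values. Without 5xFAD library 1, the difference in the share of the 10 largest clones was -4.98 percentage points and the log2 difference in the effective number was 0.66 (2.36 without 5xFAD library 2), and without the largest clone of each library they were -3.71 and 0.45. When cells with 2 TRB chains were kept, the log2 effective number of 5xFAD;Cxcr6-/- library 1 fell to 6.88, below the 7.54 of 5xFAD library 2, and the differences in the expanded share and in the share of the 10 largest clones were -8.27 and -5.38 percentage points.

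**Figure D1:**
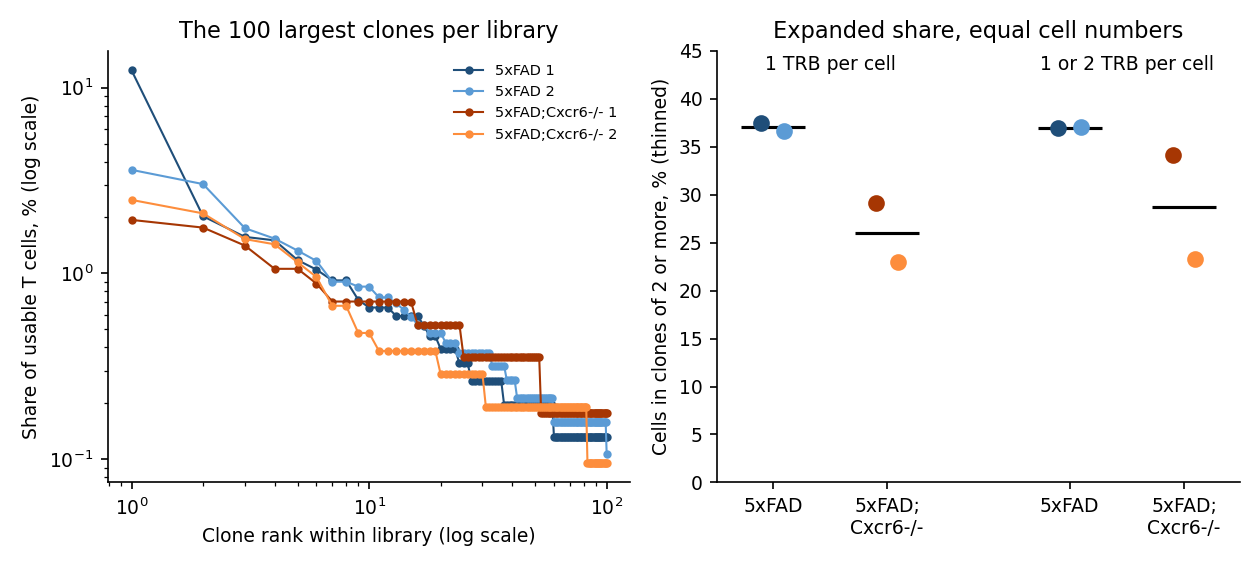
Left, share of usable T cells (%, log scale) against clone rank (log scale) for the 100 largest clones of each library, where the largest clone of 5xFAD library 1 stands at 12.4%. Right, thinned share of cells in clones of 2 or more (%) per library (points) with the genotype mean (line), for cells with 1 TRB and for cells with 1 or 2 TRB, where with 1 TRB the means are 37.1% in 5xFAD and 26.02% in 5xFAD;Cxcr6-/-.

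The largest clone of the series came from 5xFAD library 1 and held 189 cells, 12.4% of usable cells (95% Clopper-Pearson interval 10.8 to 14.1). Its TRB joined TRBV16 (GRCm38, chromosome 6, 41151740 to 41152230, TR_V_gene) to TRBJ2-1 with the CDR3 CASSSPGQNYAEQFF, and its TRA joined TRAV9D-3 to TRAJ22 with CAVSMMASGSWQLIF. The next clones of that library held 31 cells (TRBV12-1, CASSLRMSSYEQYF) and 24 cells (TRBV3, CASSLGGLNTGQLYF). In 5xFAD library 2 the 3 largest clones held 68 cells (TRBV12-2, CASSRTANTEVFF), 57 cells (TRBV16, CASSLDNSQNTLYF) and 33 cells (TRBV12-2, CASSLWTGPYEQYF). The largest of these made up 3.61% of usable cells (95% Clopper-Pearson interval 2.81 to 4.55).

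In 5xFAD;Cxcr6-/- library 1 the 3 largest clones held 11 cells (TRBV12-2+TRBV13-2, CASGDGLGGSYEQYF), 10 cells (TRBV17, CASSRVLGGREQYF) and 8 cells (TRBV13-3, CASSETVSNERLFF). The TRBV17 chain was present in 51 cells in all, most of which carried a second TRB chain and were not usable, and with those cells kept its clone held 47 cells. In 5xFAD;Cxcr6-/- library 2 the 3 largest clones held 26 cells (TRBV10, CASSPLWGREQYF), 22 cells (TRBV12-2, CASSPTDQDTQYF) and 16 cells (TRBV12-2+TRBV13-2, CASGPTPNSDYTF). The 26-cell clone was 2.49% of usable cells (95% Clopper-Pearson interval 1.63 to 3.62). The joined name TRBV12-2+TRBV13-2 is a label of the deposited tables, and its V sequence equalled that of TRBV13-2 and not that of TRBV12-2.

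Cells with the invariant chain of natural killer T cells were rarer in the 5xFAD;Cxcr6-/- libraries. This chain joins TRAV11 to TRAJ18 and recognises lipids on CD1d, and the cells that carried it are called iNKT-like here because no expression data were used. They made up 13.9% (213 cells, 95% Clopper-Pearson interval 12.2 to 15.8) and 8.38% (158 cells, 7.17 to 9.73) of usable cells in the 5xFAD libraries. In the 5xFAD;Cxcr6-/- libraries they made up 4.06% (23 cells, 2.59 to 6.02) and 1.82% (19 cells, 1.10 to 2.82). No interval of one genotype overlapped an interval of the other.

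The mean share of iNKT-like cells was 11.2% ± 3.94 (SD, n = 2) in 5xFAD and 2.94% ± 1.58 (SD, n = 2) in 5xFAD;Cxcr6-/-, a ratio of 3.802 and a difference of -8.23 percentage points that exceeded the spread between replicates (exact two-sided permutation p = 0.333). Counted by clones, the shares were 19.9% and 12.6% in 5xFAD against 5.07% and 2.29% in 5xFAD;Cxcr6-/-, a mean difference of -12.6 percentage points. Without 5xFAD library 1 the difference in the share of cells was -5.45 percentage points.

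Most iNKT-like cells of every library carried the same TRA CDR3, although only 23 and 19 such cells describe the 5xFAD;Cxcr6-/- libraries. The sequence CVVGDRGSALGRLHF was carried by 93.9% and 98.1% of these cells in the 5xFAD libraries and by 91.3% and 94.7% in the 5xFAD;Cxcr6-/- libraries. TRBV13-2, the main partner of the invariant chain in mice, was used by 59.6% and 45.6% of iNKT-like cells in 5xFAD and by 43.5% and 52.6% in 5xFAD;Cxcr6-/-, with both labels of this segment counted. Among all other clones TRBV13-2 was used by 8.75%, 10.3%, 12.1% and 10.4% in the 4 libraries. Expanded iNKT-like clones numbered 9 of 190 and 6 of 144 in the 5xFAD libraries, where the largest held 9 and 7 cells. In the 5xFAD;Cxcr6-/- libraries they numbered 0 of 23 and 0 of 19, too few clones to show a lack of expansion.

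**Figure D2:**
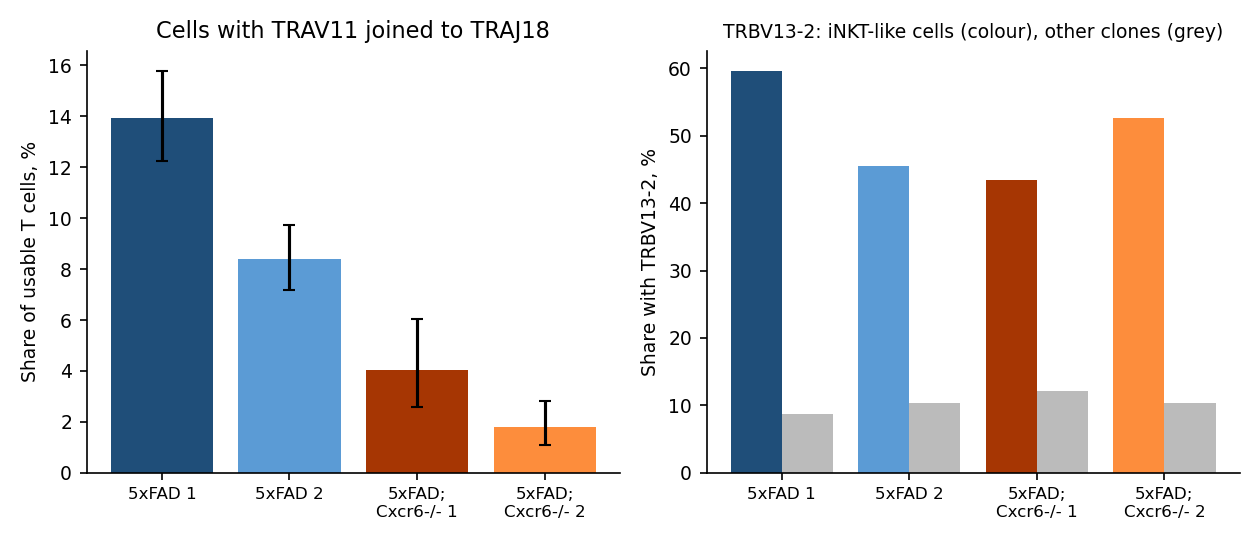
Left, share of usable T cells with TRAV11 joined to TRAJ18 (%) per library, with 95% Clopper-Pearson intervals as error bars, where the 5xFAD bars stand at 13.9% and 8.38% and the 5xFAD;Cxcr6-/- bars at 4.06% and 1.82%. Right, share (%) that used TRBV13-2 among iNKT-like cells (coloured bars) and among other clones (grey bars), with 59.6% against 8.75% in 5xFAD library 1.

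Cells with TRAV1 joined to TRAJ33, the chain of mucosal-associated invariant T cells that recognise vitamin B metabolites on MR1, were at the edge of detection. They numbered 2 of 1527 and 6 of 1885 in the 5xFAD libraries, 0.131% (95% Clopper-Pearson interval 0.0159 to 0.472) and 0.318% (0.117 to 0.692). In the 5xFAD;Cxcr6-/- libraries 0 of 567 and 0 of 1046 cells carried it, which allows shares of up to 0.529% and 0.287%. A difference between genotypes was not detectable at this depth.

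The segments of the invariant chain were the ones whose use by clones differed between genotypes. Each clone was counted once, so that a large clone weighed no more than a small one. TRAV11 (GRCm38, chromosome 14, 53519303 to 53519859, TR_V_gene) was used by 16.6% ± 5.20 of clones in 5xFAD and by 3.85% ± 2.03 in 5xFAD;Cxcr6-/- (SD, n = 2). TRAJ18 (chromosome 14, 54200777 to 54200842, TR_J_gene) was used by 18.3% ± 5.48 and 5.96% ± 2.47 of clones. Both segments were lower in both 5xFAD;Cxcr6-/- libraries than in either 5xFAD library.

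Among 149 V and J segments, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05 called these 2, both lower in 5xFAD;Cxcr6-/-, and 12 segments had an unadjusted p under 0.05. The log2 fold change was -2.23 (SE 0.25, edgeR adjusted p = 1.15e-14) for TRAV11 and -1.70 (SE 0.23, edgeR adjusted p = 1.35e-10) for TRAJ18. DESeq2 called the same 2 segments, at -2.17 (SE 0.46, DESeq2 adjusted p = 0.000397) and -1.65 (SE 0.42, DESeq2 adjusted p = 0.0072). The SE of the 2 tools are computed differently. TRAV11 varied within genotypes, with 20.3% and 12.9% of clones in the 5xFAD libraries and 5.29% and 2.41% in the 5xFAD;Cxcr6-/- libraries. Because edgeR estimated the spread jointly over segments, its p-values can be too small for such a segment.

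Both calls ended when 1 of the 5xFAD libraries was left out. TRAV11 was then at -1.86 without 5xFAD library 1 (edgeR adjusted p = 0.945) and at -2.51 without 5xFAD library 2 (edgeR adjusted p = 0.561), within a range of adjusted p from 5.15e-16 to 0.945 over 13 alternatives. TRAJ18 stood at -1.35 and -1.97 in these fits. With cells counted in place of clones, edgeR called 0 segments (11 at an unadjusted p under 0.05), while TRAV11 stayed at -1.93 (SE 0.50) and TRAJ18 at -1.38 (SE 0.42), with wider errors. With identical chains counted once, edgeR also called 0 segments, and the folds shrank to -0.57 (SE 0.48) for TRAV11 and -0.24 (SE 0.27) for TRAJ18. In that count the clones with the same invariant chain collapse to a few chains. Without iNKT-like clones edgeR called 0 segments (8 at an unadjusted p under 0.05), with TRAJ18 at -0.11 (SE 0.34) and TRAV11 at -1.40 (SE 1.26). Since iNKT-like clones are defined by these segments, the setting takes their clones out by construction, and the lost calls are no test of them. DESeq2 was run only on all clones, where it called 2.

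No other segment passed the threshold. TRBV10 (chromosome 6, 41091940 to 41092228) was used by 2.74% ± 0.326 of clones in 5xFAD and 4.83% ± 0.0188 in 5xFAD;Cxcr6-/- (SD, n = 2, log2 fold change 0.81, SE 0.28, edgeR adjusted p = 0.232). The annotation lists TRBV10 as TR_V_pseudogene, although productive TRBV10 chains were present in all 4 libraries. TRAJ15 (log2 fold change 0.69) and TRAV19 (1.02) had the next smallest p-values among segments that were higher in 5xFAD;Cxcr6-/-, and TRAJ16 (-1.32) followed TRAV11 and TRAJ18 among those that were lower. Their edgeR adjusted p was 0.615 each. TRAJ15 changed sign to -0.21 without 5xFAD;Cxcr6-/- library 2. Of the MAIT-like segments, TRAV1 had a log2 fold change of 0.17 (SE 0.62) and TRAJ33 of 0.44 (SE 0.30), with edgeR adjusted p of 0.934 and 0.631.

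The segments used most were ranked by their mean share of clones over the 4 libraries, and the order within a genotype can differ. TRBJ2-7 (chromosome 6, 41543810 to 41543856, TR_J_gene) was used by 21.4% ± 0.760 of clones in 5xFAD and 21.1% ± 1.67 in 5xFAD;Cxcr6-/- (SD, n = 2). TRBJ1-1 (11.7% in 5xFAD and 10.98% in 5xFAD;Cxcr6-/-) and TRBJ2-5 (10.9% and 11.4%) were next in that mean. TRBV12-2+TRBV13-2 (chromosome 6, TRBV13-2 at 41121396 to 41121832, TR_V_gene) was the most used TRBV label, with 14.4% ± 1.28 and 10.4% ± 1.45 (log2 fold change -0.48, SE 0.21, edgeR adjusted p = 0.615). Of its clones, 96 of 146 and 66 of 154 in 5xFAD were iNKT-like, against 8 of 52 and 9 of 78 in 5xFAD;Cxcr6-/-. By the same mean, the next TRBV segments were TRBV3, TRBV19, TRBV13-3 and TRBV13-1, and the TRAV segments after TRAV11 were TRAV6-6, TRAV12-2, TRAV13-1 and TRAV16N. TRAJ22 and TRAJ31 followed TRAJ18 among TRAJ segments. The edgeR adjusted p of TRBV13-1, with 7.79% of clones in 5xFAD and 5.52% in 5xFAD;Cxcr6-/-, was 0.615.

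Expanded and single clones of the same library were compared to ask which receptors took part in expansion. Chains with TRAV11 or TRAJ18 made up a smaller share of expanded clones than of single clones. TRAV11 was used by 2.97% of expanded clones and 11.4% of single clones (means of 4 libraries), and TRAJ18 by 4.99% and 13.2%. TRBV20 (GRCm38, chromosome 6, 41188273 to 41188977, TR_V_gene) was used by 1 of 446 expanded clones, which is 0.221% as a mean over libraries, and by 3.27% of single clones. Over all libraries, 1 of 446 expanded clones against 91 of 2938 single clones was a ratio of shares of 0.0724 (95% interval 0.00181 to 0.414, exact binomial, counting error only). Each of the 3 was lower among expanded clones in 4 of 4 libraries.

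Those 3 segments were the ones that edgeR called in a model with the library as a block, and 14 of 149 had an unadjusted p under 0.05. With TMM scaling edgeR called 8 segments, all lower among expanded clones, and these 3 were among them. The log2 fold change of expanded over single clones was -1.90 (SE 0.32, edgeR adjusted p = 1.44e-06) for TRAV11, -1.42 (SE 0.28, edgeR adjusted p = 4.79e-05) for TRAJ18 and -3.63 (SE 0.91, edgeR adjusted p = 0.0040) for TRBV20. DESeq2 called 2 segments and left TRBV20 out at a similar fold (-3.39, SE 1.10, DESeq2 adjusted p = 0.10). Over 12 alternatives TRBV20 ranged from -6.75, without 5xFAD library 1, where 0 expanded TRBV20 clones remained, to -1.15, with distinct chains, and its adjusted p by edgeR or DESeq2 from 0.000404 to 0.256. Without the iNKT-like clones, TRBV20 alone was called at -3.77, with TRAJ18 at -0.018 (SE 0.54) and TRAV11 at -0.64 (SE 1.35). That setting takes out clones with TRAV11 and TRAJ18 by construction.

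Several libraries and settings decided these calls. TRBV20 was no longer called without 5xFAD library 2 (-2.82, SE 1.01, edgeR adjusted p = 0.256) or without 5xFAD;Cxcr6-/- library 1 (-3.40, SE 1.07, edgeR adjusted p = 0.0780). TRAJ18 was not called without 5xFAD library 2 (-1.31, SE 0.38, edgeR adjusted p = 0.0525). TRBV20 was also not called when expansion meant 3 or more cells (edgeR adjusted p = 0.0989), a size that 0 TRBV20 chains reached. The fitted fold there (-6.63, SE 2.13) was larger with a wider error, and at 0 counts it depends on the prior count and is no bound. When identical chains of different clones were counted once, TRAV11 and TRAJ18 changed sign to 2.20 and 1.13, because the many clones with the same invariant chain then collapse to a few chains.

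Whether expansion favoured different segments in the genotypes was tested as an interaction. In edgeR 0 segments were called, with 2 at an unadjusted p under 0.05, and DESeq2 called 0, with 3 at an unadjusted p under 0.05. The 5xFAD;Cxcr6-/- libraries held only 52 and 82 expanded clones. Errors of the log2 estimates were wide, as for TRAV11 (-5.32, SE 3.66) and TRBV20 (-3.79, SE 4.81). The interaction was not among the simulated tests. The lack of calls therefore does not show that expansion favoured the same segments.

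**Figure D3:**
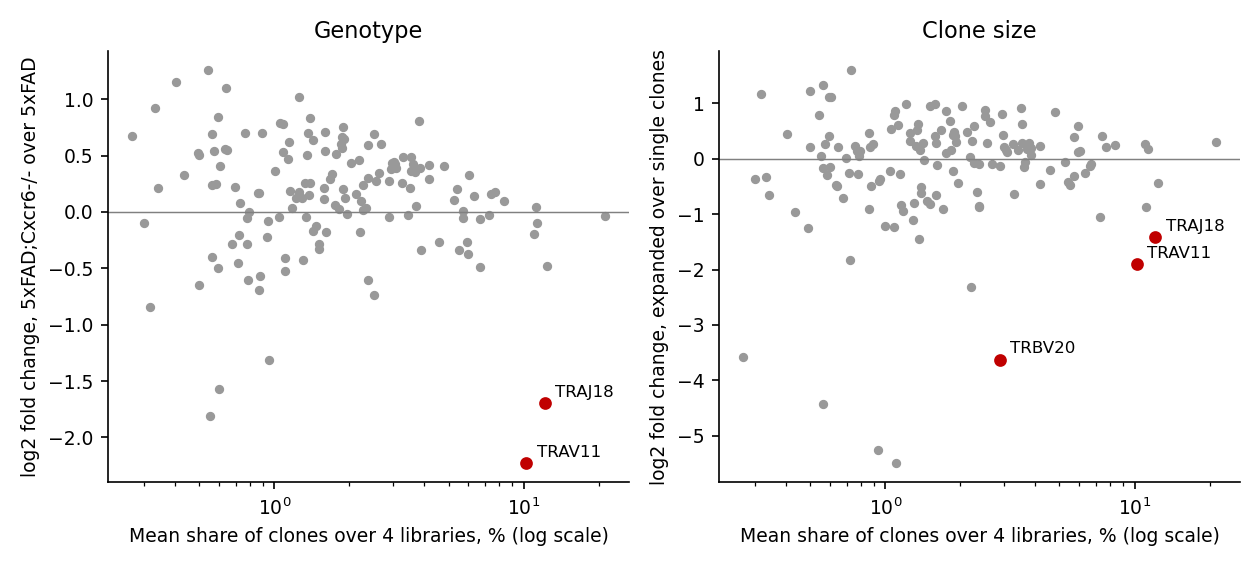
Log2 fold change of the number of clones per V or J segment against the mean share of clones over 4 libraries (%, log scale), for 5xFAD;Cxcr6-/- over 5xFAD (left) and for expanded over single clones (right), where each point is 1 of 149 segments and red points are those edgeR called at an adjusted p under 0.05. TRAV11 lies at -2.23 on the left and -1.90 on the right, and TRBV20 lies at -3.63 on the right.

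In a developing T cell the first rearrangements of the TRA locus use J segments at its 5' end, and later rearrangements move towards the 3' end. Clones of the 5xFAD libraries used the 3' group, TRAJ20 to TRAJ2, in 40.9% and 33.2% of cases. In 5xFAD;Cxcr6-/- this share was 25.8% and 23.5%, and the means were 37.1% ± 5.43 and 24.6% ± 1.61 (SD, n = 2, exact permutation p = 0.333). Use of the 5' group, TRAJ58 to TRAJ40, was 21.8% ± 1.82 and 28.2% ± 1.22 (SD, n = 2, exact permutation p = 0.333). Most of the 3' difference of -12.4 percentage points went with TRAJ18, since it was -3.16 without iNKT-like clones, and the 5' difference of 6.38 became 3.25. The TRBJ1 cluster was used by 35.1% ± 0.745 and 36.3% ± 2.82 of clones (SD, n = 2, exact permutation p = 1), within the spread between replicates. Segments that can serve TRA or TRD, named TRAV/DV, were used by 6.86% ± 0.0605 and 8.02% ± 0.753 of clones (SD, n = 2, exact permutation p = 0.333). That difference of 1.16 percentage points was 0.628 without 5xFAD;Cxcr6-/- library 2 and 0.114 without iNKT-like clones, and changed sign to -0.399 with cells counted. The constant segment TRBC1 was carried by 29.3% and 34.8% of cells in 5xFAD and by 38.2% and 34.0% in 5xFAD;Cxcr6-/- (exact permutation p = 0.667).

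The TRB CDR3, the loop that contacts peptide, had the same mean length in both genotypes within the spread between libraries. Lengths were 14.0 and 13.8 residues in 5xFAD and 13.8 and 13.9 in 5xFAD;Cxcr6-/-, a difference of -0.0753 (exact permutation p = 0.667) that changed sign without 5xFAD library 1. The central CDR3 residues of clones had a mean Kyte-Doolittle hydrophobicity of -1.27 ± 0.0124 in 5xFAD and -1.31 ± 0.00578 in 5xFAD;Cxcr6-/- (SD, n = 2, exact permutation p = 0.333). Their net charge was -0.811 ± 0.0286 and -0.762 ± 0.0117 (SD, n = 2, exact permutation p = 0.333).

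No clone was found in more than 1 library. Of the 6 pairs of libraries, 0 shared a clone by TRB and TRA nucleotides, including the 2 pairs of the same genotype, and 0 barcodes present in 2 libraries carried the same chain. Even clones of 189 cells (5xFAD library 1) and 26 cells (5xFAD;Cxcr6-/- library 2) were absent from the other library of their genotype. This argues against replicate libraries being portions of the same cell suspension, while single and pooled mice cannot be told apart. TRB nucleotide sequences were shared 3 times and TRB amino-acid sequences 49 times over the 6 pairs, with 4 to 13 per pair. A shuffle of library labels can place both copies of a sequence in the same library, which the data cannot, since each sequence counted once per library. Shuffled numbers thus tend to lie low by construction, and a count above their mean says nothing about sharing. For the 5xFAD libraries 13 TRB amino-acid sequences were shared, where shuffled library labels gave a mean of 9.05 (95% of draws from 4 to 14). For the 5xFAD;Cxcr6-/- libraries 5 were shared, where shuffling gave 3.19 (0 to 7). TRA nucleotide sequences were shared 65 times in all and 36 times without iNKT-like clones. In 2 of the 6 pairs the number was above the shuffled range, which is no evidence of excess sharing because that range lies low. The number was 16 between the 5xFAD libraries (shuffled 4 to 14) and 14 between 5xFAD library 1 and 5xFAD;Cxcr6-/- library 2 (3 to 12). Without iNKT-like clones these pairs shared 10 (shuffled 2 to 10) and 9 (1 to 9). Across the 91 V segments found in all 4 libraries, 0 differed in their commonest germline sequence.

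More TRA transcripts were captured per cell in the 5xFAD;Cxcr6-/- libraries, by the mean though not by the median. The median was 4 UMIs per TRA chain in every library and 10, 9, 10 and 10 UMIs per TRB chain. Mean TRA UMIs per usable cell were 4.29 ± 0.0716 in 5xFAD and 5.12 ± 0.00878 in 5xFAD;Cxcr6-/- (SD, n = 2, exact permutation p = 0.333). The median reads per TRA chain were 3507 and 3367 in 5xFAD and 8088 and 5024 in 5xFAD;Cxcr6-/-. Barcodes without a TRA chain made up 19.96% and 18.4% of barcodes in 5xFAD and 15.3% and 15.3% in 5xFAD;Cxcr6-/-. Within libraries, the mean TRA UMIs of expanded clones over single clones were in a ratio of 1.04 ± 0.0364 (SD over 4 libraries, higher in 3 of 4, exact permutation p = 0.25).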

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

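All comparisons in this part were chosen after the values had been seen, except the edgeR interaction test, which was planned.

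In 3 of 34 measures, the difference between expanded and single clones went one way in both 5xFAD libraries and the other way in both 5xFAD;Cxcr6-/- libraries. Chance gives such opposite signs in 12.5% of measures with 2 libraries against 2. The label TRBV12-2+TRBV13-2 was lower among expanded than single clones in 5xFAD, with differences of -6.28 and -6.56 percentage points, and higher in 5xFAD;Cxcr6-/-, with 0.0957 and 4.46. The genotypes differed by 8.70 percentage points on average. The separate label TRBV13-2, which has the same V sequence, was lower among expanded clones in 4 of 4 libraries. In 5xFAD;Cxcr6-/- library 1 it was used by 0% of expanded and 2.49% of single clones. With both labels joined, that library would be lower among expanded clones, as in 5xFAD, so the opposite signs depend on the split label. Of the clones labelled TRBV12-2+TRBV13-2, 96 of 146 and 66 of 154 in the 5xFAD libraries were iNKT-like. In the 5xFAD;Cxcr6-/- libraries 8 of 52 and 9 of 78 were. Since iNKT-like clones were mostly single, the contrast may follow their share, and these percentage points were not recomputed without them. TRAJ33 was higher among expanded clones in 5xFAD, by 1.40 and 1.37 percentage points, and lower in 5xFAD;Cxcr6-/-, with -3.23 and -0.352, and the genotypes differed by -3.18. For these 2 segments the edgeR interaction test gave an adjusted p of 1, with log2 estimates of 1.16 and -1.36.

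The TRAV/DV group was higher among expanded clones in 5xFAD, by 1.20 and 0.871 percentage points, and lower in 5xFAD;Cxcr6-/-, with -1.94 and -2.73. The difference between the genotypes, -3.37 percentage points, was not tested. Only 52 and 82 expanded clones stand behind the 5xFAD;Cxcr6-/- values.

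Cells with 2 TRB chains, which the comparisons left out, held repeated pairs of TRB chains in the 5xFAD;Cxcr6-/- libraries. In 5xFAD;Cxcr6-/- library 1, 37 of 61 such cells carried the same pair, TRBV17 with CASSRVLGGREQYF and TRBV23 with the short CDR3 CSSSRQ. All 37 also carried the TRA of TRAV6N-7 and TRAJ17 with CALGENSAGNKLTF, and 0 of them had a second TRA chain. In 5xFAD;Cxcr6-/- library 2, 8 of 55 such cells shared TRBV29 with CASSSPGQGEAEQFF and TRBV3 with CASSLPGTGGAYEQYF, all with the same TRA. The most frequent pair was found in 2 and 3 cells in the 5xFAD libraries. Cells with 2 TRB made up 3.96%, 3.49%, 7.97% and 4.14% of barcodes in the 4 libraries, and 3.87%, 3.37%, 3.14% and 3.53% outside the commonest pair. No biological or technical explanation was tested for these pairs.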

How the results depend on the processing

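Keeping cells with 2 TRB, dropping short TRB CDR3s first, clones by CDR3 nucleotides alone, leaving out the largest clones (for the expanded share and effective number), leaving out iNKT-like clones from the segment and J group results, 3 UMIs per TRA for invariant cells, crossed replicate numbers and DESeq2 for the interaction were chosen only after the data were seen. Of 281 alternatives over 28 results, 221 kept their direction and their side of the threshold or moved by less than the replicate spread, 32 moved by more, 18 lost a call and 10 reversed. The 221 include settings that change few or no cells and segments called in neither setting, so their number does not measure robustness. Where no construction is named, the cause was not tested.

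All 53 alternatives of the 3 clonality results kept the direction of the mean difference, though not always the separation of the libraries, and 46 stayed within the spread. Among them, leaving out barcodes that carried the same clone in another library removed no cell, so that setting could not differ. The expanded share differed by -14.7 percentage points without iNKT-like and MAIT-like cells, by -18.5 without thinning, where larger libraries show more expansion by construction, and by -7.75 without the largest clones. The share of the 10 largest clones then differed by -3.71 and the log2 effective number by 0.45. On other scales the diversity difference was 0.54 (log2 exponential Shannon) and -0.0989 (Gini). By clones, the iNKT-like difference was -12.6 and the MAIT-like difference -0.367 percentage points. The MAIT-like difference was -0.0752 with 3 UMIs per TRA and ranged from -0.318 to -0.131 when 1 library was left out.

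Among the J groups, counting cells gave 3.89 percentage points for TRBJ1, 0.443 for the middle TRAJ group, -6.51 for the 3' group and a reversed -0.399 for TRAV/DV. Without iNKT-like clones, the 5' group was at 3.25, the 3' group at -3.16, TRAV/DV at 0.114 and the middle group reversed to -0.0852. Leaving out 1 library gave -0.805 (without 5xFAD;Cxcr6-/- library 1) to 3.18 for TRBJ1, -0.165 to 0.0146 residues for CDR3 length (reversed without 5xFAD library 1), and 0 to 1 for the median TRB UMIs. In reads per chain, the TRA and TRB medians differed by 3119 and 9408. Sharing by TRB nucleotides alone gave 3 sequences.

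In the genotype test of segments, edgeR called 0 with distinct chains, cells counted or without iNKT-like clones (10, 11 and 8 at an unadjusted p under 0.05), against 2 with clones and 2 by DESeq2. With cells counted the folds stayed at -1.93 (TRAV11) and -1.38 (TRAJ18), and with distinct chains they were -0.57 and -0.24. Leaving out iNKT-like clones takes out clones with TRAV11 and TRAJ18 by construction. Leaving out 1 library gave 0 to 2 calls, and 0 without either 5xFAD library, where the lone library is assumed to vary like the other genotype. With the replicate number as a block, edgeR called 2 segments, the same 2 as without it. The numbers mark no stated pairing (r = -0.141 over 149 segments), and the crossed replicate block called 2. TRAV1 reversed to -0.032 without iNKT-like clones. With 1 library left out, TRAV1 ranged from -0.33 (without 5xFAD;Cxcr6-/- library 1) to 0.78 and TRAJ15 from -0.21 (without 5xFAD;Cxcr6-/- library 2) to 1.04.

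Between expanded and single clones, edgeR called 8 with TMM, 7 with distinct chains and 1 without iNKT-like clones, and 1 (without 5xFAD library 2) to 4 (without 5xFAD library 1) when a library was left out. With distinct chains TRAV11 and TRAJ18 reversed to 2.20 and 1.13, since invariant chains collapse by construction. Without iNKT-like clones, both lost their call after clones defined by them were taken out. Depth limits a 0 count to shares under 0.196%, 0.159%, 0.529% and 0.287% in the 4 libraries.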

Other observations

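The thinned share, the share of clones, the count of distinct chains, the sharing of sequences and the CDR3 comparisons were planned, and the test of TRBV20 capture was chosen before its result was seen, while the other tests, and the use of the planned values to weigh explanations, were chosen only after the results were seen.

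By library means, the TRB CDR3 loops of expanded clones had a less hydrophilic and less acidic centre than those of single clones, by an uneven amount. Central hydrophobicity on the Kyte-Doolittle scale was higher by 0.101 ± 0.0888 (SD over 4 libraries, higher in 4 of 4, exact permutation p = 0.125, the smallest that 4 libraries allow). Net charge was higher by 0.101 ± 0.0682 (higher in 4 of 4, exact permutation p = 0.125). In 5xFAD library 1 the differences were small, with hydrophobicity of -1.235 against -1.260 and charge of -0.823 against -0.833. The iNKT-like clones, which were mostly single, were not left out of this comparison. CDR3 length differed by -0.0777 ± 0.205 residues, with 2 libraries in each direction (exact permutation p = 0.5).

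Only 2 TRB amino-acid sequences were found in 3 libraries and 0 in all 4. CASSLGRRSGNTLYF was built from TRBV3 and TRBJ1-3 by 3 clones of 13 cells, each with its own nucleotide sequence, and the largest of these clones held 11 cells. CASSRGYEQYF was found in 3 clones of 1 cell each. Among TRA sequences 13 were found in at least 3 libraries and 1, the invariant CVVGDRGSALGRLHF, in all 4, where 7 nucleotide sequences in 357 clones encoded it. Besides TRBV13-2, iNKT-like cells used TRBV29 in 14.1% and 15.2% of cells in 5xFAD and in 21.7% and 10.5% in 5xFAD;Cxcr6-/-, against 3.70% to 6.03% of other clones over the 4 libraries. TRBV29 was picked after its values were seen.

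The share of iNKT-like cells was lower in both 5xFAD;Cxcr6-/- libraries. Weaker capture of TRA chains was not seen there, since mean TRA UMIs per usable cell were higher by 0.825 in 5xFAD;Cxcr6-/-. Crowding out by expanded clones would need them to hold more of the 5xFAD;Cxcr6-/- repertoire, where they held less, and the share of clones, which counts each clone once, also differed by -12.6 percentage points. Differences between mice or preparations cannot be told apart from the genotype, because the labels do not say which animals each library holds, and the exact permutation p of 0.333 is fixed by the design and decides nothing. An effect of Cxcr6 loss on these cells may underlie the difference and stays untested beyond this.

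Less of the repertoire lay in expanded clones in 5xFAD;Cxcr6-/-. The number of cells sampled was not the whole cause, since the thinned difference was -11.0 percentage points with a pooled SD of 3.105. The mean difference was -7.75 (pooled SD 4.30) without the largest clones and -8.27 (pooled SD 5.39) with cells of 2 TRB kept. In these settings 5xFAD;Cxcr6-/- library 1 came close to 5xFAD library 1, with 27.7% against 29.4% and 34.1% against 36.9%. The difference then rested more on 5xFAD;Cxcr6-/- library 2, with 20.9% and 23.3%. A pooled SD from 2 libraries per genotype can exclude neither explanation. For the effective number of clones, omission of cells with 2 TRB is a candidate explanation, since the log2 difference was 0.83 with them kept, within the pooled SD of 1.06. The largest clones are another candidate, since the log2 difference was smaller still without the largest clone of each library. Genotype and differences between mice stay open, and both exceptions removed together were not tested.

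TRBV20 was almost absent from expanded clones. Poor capture of its chain would leave cells with only the TRA of a TRBV20 clone. For 92 clones 1 such cell was found, 0.0109 per clone (95% upper bound 0.0606) against 0.0243 for other clones. The rate of other clones would give 2.24 cells, too few to tell the rates apart. Median UMIs of TRBV20 and other TRB chains were 8 and 10, 7 and 9, 9.5 and 10, and 11 and 10 in the 4 libraries. Weaker capture of TRBV20 chains is therefore not excluded. To test loss of cells without a TRA, all TRB chains were counted, and 8 of 121 TRBV20 chains (6.61%) and 592 of 4299 others (13.8%) were found in 2 or more cells, a permutation p of 0.019. In 3 or more cells 0 and 277 (6.44%) were found, where permutation gave a mean of 7.59 for TRBV20 (permutation p = 0.0008). Neither p decides, because the segment was picked for the pattern on many of the same cells, and counted by chain its log2 fold change was -1.15 (SE 0.46) in place of -3.63, with an edgeR adjusted p over all segments of 0.242, in a range of 0.000404 to 0.256 over 12 alternatives. Such loss stays open, lower expansion of cells with TRBV20 may also play a part, and their lineage was not analysed here.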
